A study of Sus scrofa with 12 samples.

How the data were processed

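RNA labelled as striatum from 12 newborn piglets was sequenced, 6 from a sham group and 6 from a group exposed to deep hypothermic circulatory arrest (DHCA). Per the labels' protocols, RNA was isolated with RNeasy columns, libraries were made with an Illumina TruSeq kit and sequencing was on a HiSeq 1500. Each library was placed in its group by its title, and the design text gives 6 piglets per group, so the p-values measure the spread between animals.

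The deposited count table holds raw counts per Ensembl gene, made by the authors with featureCounts 1.5.1 over exons of the Sscrofa11.1 annotation, per the file headers. The command in that header sets no strand option, so reads from a gene and from an overlapping antisense gene cannot be told apart. The aligner is not given in the sources used here. The table has 18 library columns, of which 12 match the samples by number, and the other 6 were not used in any step. The submitters' processing notes name featureCounts, DESeq2 and the Sscrofa11.1 build. The authors' deposited comparison table gives per gene a mean normalized signal, a log2 fold change with its standard error, a test statistic (a score) and p-values with adjusted p-values, per the file headers. It holds 21223 genes, of which 15926 have a name and 4115 have no adjusted p. In all 21223 rows of the authors' deposited table the statistic has the sign opposite to the fold change. The sign of the fold change was read as DHCA minus sham, since its correlation with the fold changes computed here was 0.967 across 14004 genes. Genes are not independent replicates, so this value only fixes the sign. In the authors' deposited table, 86 genes with 0 counts in all 12 libraries also have values, so the counts behind it were not only those analysed here, and which counts entered that fit is not given in the sources used here.

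Gene names came from the authors' deposited table and otherwise from a reference table of pig gene names, which held 14857 of the 25880 gene IDs. After both, 17449 IDs had a symbol. No reference genome was used here, so GC content was not examined. Coordinates are those of the count table.

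Counts were analysed in R 4.3.3. Genes were filtered with edgeR 4.0.16 filterByExpr by group, scaled by TMM, and tested with the edgeR quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) with group as the only term. Adjusted p is by Benjamini-Hochberg over the tested genes, with a threshold of 0.05, and the standard error of a log2 fold change was taken from the F statistic. A fold change is DHCA minus sham throughout, and CPM is counts scaled to library size after TMM.

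Before the data were examined, 34 gene lists for stress responses, metabolism and cell types were fixed. The 32 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), 2-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the rotation test fry were run as alternatives. The share of each library's counts in 14 cell type lists, in mitochondrially encoded messenger RNAs and in the 10 most abundant genes was compared by an exact 2-sided permutation test over the 924 assignments of the libraries to groups of 6, whose smallest p is 0.00216.

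The genes named were set by a rule fixed at the same time. It takes up to 10 genes per direction with the largest fold change among called genes with a symbol, at least 1 CPM on average and no overlap between groups. It adds the 10 genes with the smallest p, up to 4 members with the smallest p that moved in the direction of a called list or 3 of another list, and 22 genes fixed by name. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

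Alternatives fixed beforehand were DESeq2 size factors or upper-quartile factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, no filter, a filter of 1 CPM in 6 libraries, a block by the number in the titles, leaving out each library, leaving out mitochondrial and red cell genes, and a threshold of 0.01. Libraries doubted after inspection were left out together as later additions, namely Sham 1 and Sham 5 for low depth and Sham 4 for markers of another brain region.

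Library totals ranged from 1377809 to 12933536 counts, and 1 TMM-scaled CPM stands for 1.51 counts in the shallowest library and 13.7 in the deepest. Pairs of libraries within a group differed by a chi-square per degree of freedom between 8.50 and 125.8 over genes with at least 10 counts, so no pair looked like one library deposited more than once. The steps were tested on simulated data with the real means, spread and library sizes of this DHCA against sham comparison, in which 200 of 14004 genes were changed. After the filter was rerun on the simulated counts, 13883 genes were tested with edgeR. Any changed gene that the filter removed counted as not recovered. EdgeR recovered 35% of the genes changed 2-fold and 92% of those changed 4-fold, and called 9 unchanged genes. The DESeq2 Wald test on 14004 genes recovered 62% and 96% and called 34 unchanged genes. Sample quality weights were not tested in this way.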

Results

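The striatum, a deep forebrain region made up largely of inhibitory spiny projection neurons, was profiled by RNA sequencing in newborn pigs. Piglets of the DHCA group (n = 6) were anaesthetised with 4% isoflurane, placed on cardiopulmonary bypass through a sternotomy, cooled to 18 °C, held in circulatory arrest for 30 min, rewarmed to 37 °C on bypass and recovered for 6 h. Sham piglets (n = 6) were kept under 4% isoflurane. The comparison asks how the striatal transcriptome differed 6 h after the whole procedure, which includes surgery, bypass, cooling and arrest together. Counts per library averaged 7347277 in the sham group and 7639934 in the DHCA group. The shallowest were Sham 5 with 1377809 and Sham 1 with 2515816, and the deepest was Sham 6 with 12933536. Sham 1 and Sham 5 also had the smallest share of counts from the mitochondrial chromosome, 4.01% and 7.30% against 10.6% to 26.3% in the other 10 libraries. Their median correlation with the other libraries was 0.859 and 0.903, against 0.913 to 0.961. On the first principal component, which held 42.3% of the variance, Sham 1 lay at -113.7 and Sham 5 at -41.75, and the others between -15.51 and 45.26. Of 25880 genes in the table, 22005 had a count and 14004 were tested.

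In the striatum after DHCA, ADM, TGM3, IRF4 and SOCS3 were among the called genes with the largest rise, and SLC52A3, SLC19A3 and PCDH12 among those with the largest fall. In all, 26 genes passed the edgeR test, 19 higher and 7 lower in DHCA, and 25 of them had a log2 fold change of at least 1 in size. ADM, which encodes the vasodilator adrenomedullin (ENSSSCG00000013408, chromosome 2, 49228610 to 49231446), rose 10.8-fold, from 0.727 ± 0.127 to 8.03 ± 3.65 CPM (SD, n = 6 per group; log2 fold change 3.43, SE 0.36, adjusted p = 0.00261). SLC52A3, a riboflavin transporter (ENSSSCG00000007199, chromosome 17, 34459359 to 34481128), fell from 21.2 ± 7.01 to 3.68 ± 1.38 CPM (log2 fold change -2.52, SE 0.29, adjusted p = 0.00354). In each of the 26 genes the 6 DHCA libraries lay on one side of the 6 sham libraries. This separation was found in 139 of the 14004 tested genes (0.993%), where chance gives 0.216%.

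**Figure D1:**
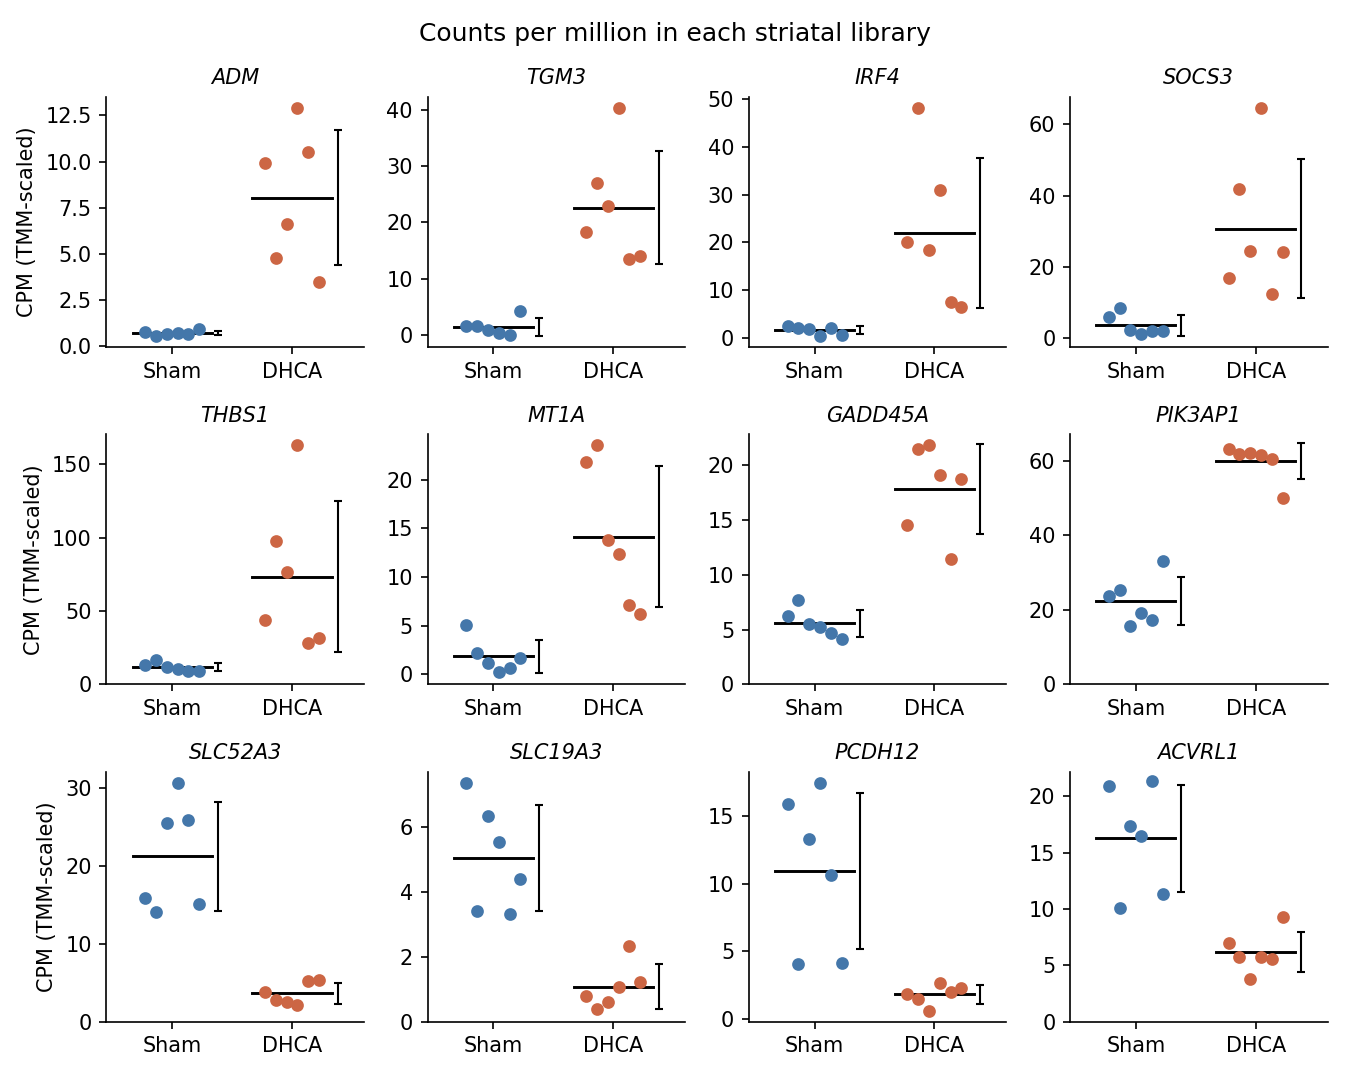
Each panel shows one gene, with a point per library (6 Sham, 6 DHCA), the vertical axis in TMM-scaled CPM, a horizontal line at the group mean and a bar of ± 1 SD. The DHCA points of ADM lie between 3.50 and 12.9 CPM, above the highest sham value of 0.952, and those of SLC52A3 lie between 2.15 and 5.36 CPM, below the lowest sham value of 14.1.

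THBS1, which encodes the matrix glycoprotein thrombospondin 1, rose from 11.8 ± 2.95 to 73.5 ± 51.5 CPM (log2 fold change 2.62, SE 0.41, adjusted p = 0.0208). PLAT, which encodes tissue plasminogen activator, rose by 1.53 on the log2 scale (SE 0.24, adjusted p = 0.023). IGFBP3, a carrier of insulin-like growth factors, rose by 2.35 (SE 0.41) and the transglutaminase gene TGM3 by 3.70 (SE 0.51). TGM3 had 0 counts in Sham 5, which allows up to 1.99 CPM there. EMP1, a membrane protein gene used as a marker of reactive astrocytes, rose from 4.44 ± 2.77 to 22.7 ± 4.50 CPM.

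IRF4, a transcription factor of lymphoid and myeloid cells, rose from 1.49 ± 0.839 to 21.9 ± 15.7 CPM (log2 fold change 4.03, SE 0.59, adjusted p = 0.0116). The adaptor genes SLA (Src-like adaptor) and PIK3AP1 rose by 2.04 (SE 0.30) and 1.41 (SE 0.19). SOCS3, a feedback inhibitor of cytokine receptors, rose by 3.04 (SE 0.52, adjusted p = 0.0341) and GADD45A, induced by DNA damage and other stress, by 1.66 (SE 0.22, adjusted p = 0.00794). The metallothionein genes MT1A and MT2A, which bind zinc and copper, rose by 3.02 (SE 0.51) and 1.27 (SE 0.23). The reference table names the MT2A gene ID MT1X, and reads can be shared among metallothionein copies, so the split between both genes is uncertain.

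SLC19A3, a thiamine transporter, fell from 5.06 ± 1.63 to 1.08 ± 0.692 CPM (log2 fold change -2.20, SE 0.38, adjusted p = 0.0341), and the organic anion transporter SLC22A6 had a log2 fold change of -1.42 (SE 0.25). PCDH12, an endothelial protocadherin, had -2.55 (SE 0.43) and ACVRL1, an endothelial receptor of bone morphogenetic proteins, -1.37 (SE 0.25). ALS2CL, a relative of the gene of the guanine nucleotide exchange factor alsin, had -2.86 (SE 0.46, adjusted p = 0.0235), with sham values spread from 5.24 to 43.3 CPM. Among the other called genes, TLR2, RAB20, FZD4, EMP2 and ENSSSCG00000022925 were higher and ENSSSCG00000036884 was lower, and these 6 were named after their values were seen.

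The number of called genes depended on single libraries and on the tool. It was 51 without Sham 2, 10 without Sham 3, 10 without Sham 4, 11 without Sham 5, 13 without DHCA 1, 9 without DHCA 2, 12 without DHCA 3 and 12 without DHCA 4. With Sham 1, Sham 4 and Sham 5 left out together, an alternative chosen after seeing the data, only ENSSSCG00000022925 (log2 fold change 1.28, adjusted p = 0.0326) was called, while the 26 genes had the same direction with a median size of 1.80 against 2.12, and 9 of them had an adjusted p under 0.10. The DESeq2 Wald test called 181 genes and limma-voom with sample quality weights 207, and both lists held all 26. On simulated data of this design DESeq2 called 34 unchanged genes and edgeR 9, and they recovered 62% and 35% of the genes changed 2-fold. Genes were drawn independently there, with no library set apart, and DESeq2 tested 14004 genes against 22005 in the real data. The simulation therefore cannot tell how many of the 181 calls are false. ADM, SLC52A3, GADD45A, PIK3AP1, TGM3, EMP1 and IRF4 were called without any 1 of the 12 libraries, and the other 12 named genes lost the call in at least 1 of those fits, with adjusted p up to 0.126. SLA lost it only without Sham 3 (adjusted p = 0.0509), THBS1 was called in 7 of the 12 fits, PLAT in 6, ALS2CL in 5, MT1A and SLC22A6 in 4 each, PCDH12, SLC19A3, SOCS3, MT2A and ACVRL1 in 3 each and IGFBP3 in 2. All 26 genes kept their direction in these fits.

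In the authors' deposited table, 220 genes had an adjusted p under 0.05, 134 with a positive and 86 with a negative fold change. All 26 genes called here were among them with the same direction. Of those 220, 209 were tested here, and all 209 had the same sign in both. The authors' deposited table gives ADM a log2 fold change of 3.27 (standard error 0.43) and SLC52A3 one of -2.57 (standard error 0.31). The deposited values and those computed here come from the same study, so they are not independent of each other. The direction of the deposited fold changes was itself set by their correlation with those computed here, so the shared direction is not separate evidence.

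Of the gene lists called higher after DHCA, that of glucocorticoid-induced genes had the largest median. Camera called 16 of 32 lists, 12 higher and 4 lower, where 7 of 100 splits of the libraries, the real one included, gave at least as many, and 0 with an estimated correlation (smallest adjusted p = 0.134, with 9 lists at an unadjusted p under 0.05). The rotation test fry called 6, all also called by camera. Glucocorticoid-induced genes rose with a median log2 fold change of 0.63 (camera adjusted p = 1.22e-09; adjusted p = 0.134 with an estimated correlation). Of its 26 members, 2 rose over all genes tested (MT1A and MT2A), and 12 rose and 1 fell when adjusted over the list alone. FKBP5, the classical glucocorticoid-induced chaperone gene, was at 60.2 ± 35.7 CPM in sham and 206 ± 47.1 CPM in DHCA (log2 fold change 1.76, SE 0.34, adjusted p = 0.0581). CEBPB had 1.51 (SE 0.34, adjusted p = 0.131) and PER1 0.70 (SE 0.25, adjusted p = 0.438). PER1 was at 291 CPM in Sham 1, 96.9 to 179 CPM in the other sham libraries and 210 to 343 CPM in DHCA.

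**Figure D2:**
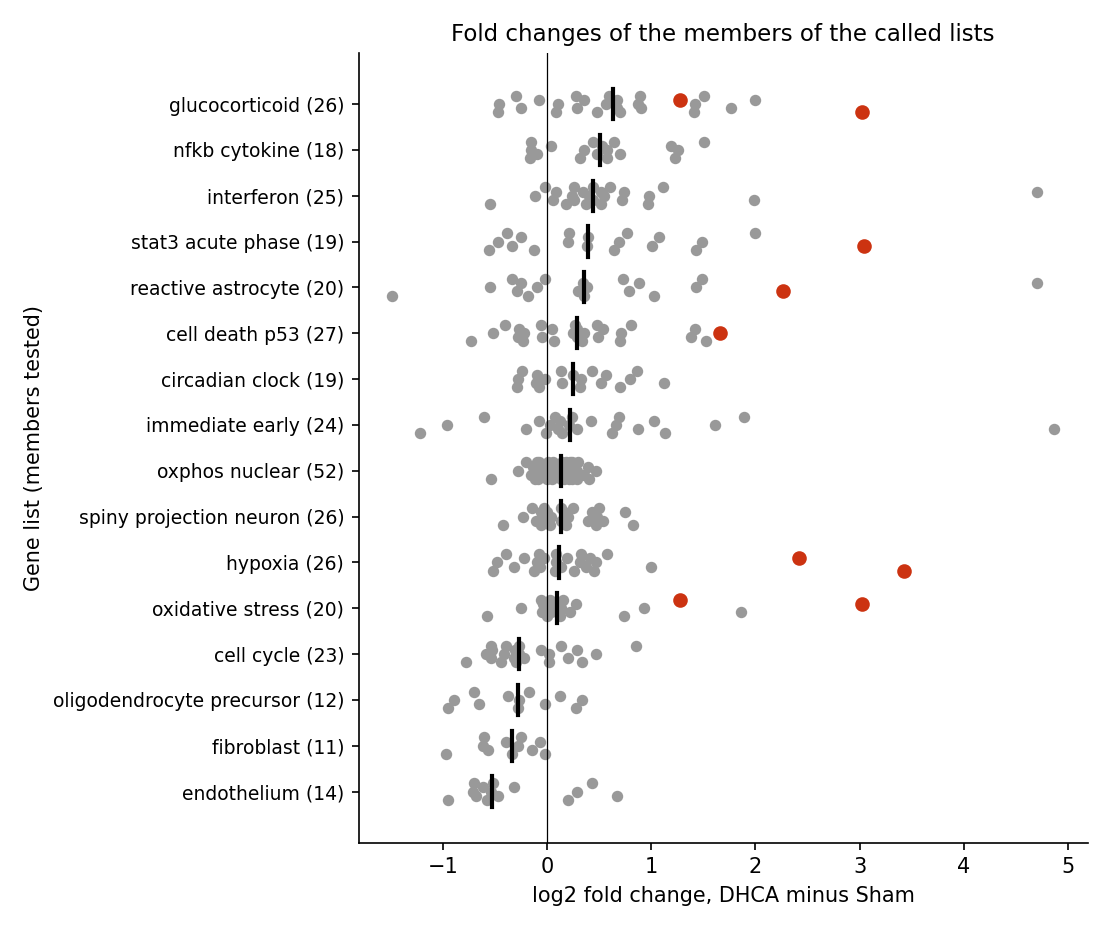
Each row is one called gene list with the number of tested members in brackets, each point is one member's log2 fold change (DHCA minus Sham), red points passed the edgeR test over all genes and the black bar is the median of the list. The medians run from -0.53 for endothelium to 0.63 for glucocorticoid-induced genes.

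Nuclear factor kappa B and cytokine genes rose (18 tested, median 0.50, adjusted p = 3.04e-05; adjusted p = 0.149 with an estimated correlation), although 0 members passed the edgeR test over all genes and 0 when adjusted over the list alone (7 higher at an unadjusted p under 0.05). Among them PTGS2 had 1.51 (SE 0.49) and TNFAIP6 had 1.26 (SE 0.35). STAT3 and acute-phase genes rose (19 tested, median 0.39, adjusted p = 0.000981; adjusted p = 0.171 with an estimated correlation), with 1 member, SOCS3, higher over all genes and 7 when adjusted over the list alone, among them STAT3 (0.64, SE 0.14), CEBPD (1.99, SE 0.47) and TIMP1 (1.43, SE 0.34). Interferon-induced genes were called higher (25 tested, median 0.44, camera adjusted p = 0.000981). With an estimated correlation, which was 0.681, camera gave adjusted p = 0.623, and fry gave 0.519. Over all genes 0 members passed (5 higher at an unadjusted p under 0.05), and 3 passed when adjusted over the list alone, CXCL10, GBP1 and GBP2. The interferon call was lost without DHCA 4 (adjusted p = 0.0532). CXCL10, a chemokine gene, ranged from 2.47 to 190 CPM across the DHCA libraries against 0.388 to 8.24 in sham (log2 fold change 4.70, SE 0.95, adjusted p = 0.0704). GBP1 had 1.99 (SE 0.53) and GBP2 had 0.97 (SE 0.25). Genes of reactive astrocytes rose (20 tested, median 0.35, adjusted p = 0.00465; adjusted p = 0.145 with an estimated correlation), with EMP1 higher over all genes, and 5 higher and 1 lower when adjusted over the list alone, OSMR (1.48, SE 0.38) among those higher. Of the fold changes 12 were positive and 8 negative, with GFAP (-0.29, SE 0.27) among the negative. TIMP1 and OSMR also stand in the STAT3 list and CXCL10 in the interferon list, so these lists are not separate evidence.

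In the hypoxia list (26 tested, median 0.11, adjusted p = 0.00436; adjusted p = 0.134 with an estimated correlation), 2 members rose over all genes, ADM among them, and 4 members, with STC2 (1.00, SE 0.23) among them, when adjusted over the list alone. VEGFA, a classical hypoxia-induced gene, had 0.086 (SE 0.29, adjusted p = 0.949), and -0.022 to 0.45 over the fits without 1 library. It was at 84.5 CPM in Sham 1, 24.5 to 44.6 CPM in the other sham libraries and 30.1 to 51.7 CPM in DHCA. Cell death and p53 genes rose (27 tested, median 0.28, adjusted p = 0.000981; adjusted p = 0.145 with an estimated correlation), with GADD45A over all genes and 5 when adjusted over the list alone, including MCL1 (0.70, SE 0.16), a survival gene, and CDKN1A (1.38, SE 0.36), which halts the cell cycle. Oxidative stress genes rose (20 tested, median 0.097, adjusted p = 0.00563; adjusted p = 0.145 with an estimated correlation), with MT1A and MT2A over all genes, and 4 higher and 1 lower when adjusted over the list alone, SOD2 (0.93, SE 0.23) and OSGIN1 (1.86, SE 0.38) among those higher. MT1A and MT2A stand in both this list and the glucocorticoid list. Circadian clock genes rose (19 tested, median 0.25, adjusted p = 0.0027; adjusted p = 0.134 with an estimated correlation), with 0 members over all genes (6 higher at an unadjusted p under 0.05) and 4 when adjusted over the list alone, CIART (0.86, SE 0.20), NFIL3 (1.12, SE 0.29), BHLHE40 (0.80, SE 0.26) and NR1D1 (0.52, SE 0.16). A recovery time was recorded for DHCA (6 h) but not for sham, so an unequal hour of collection cannot be told apart from DHCA here.

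Activity genes, spiny neuron markers and respiratory chain genes were called higher, and each call was lost without at least 1 library. Immediate early genes rose (24 tested, median 0.23, adjusted p = 0.0048; adjusted p = 0.623 with an estimated correlation), with 0 members over all genes (6 higher and 1 lower at an unadjusted p under 0.05), and 2 higher and 1 lower when adjusted over the list alone. NPAS4, an activity-dependent transcription factor gene, had 4.87 (SE 1.34, adjusted p = 0.235), with 136 CPM in DHCA 2 and 79.0 CPM in DHCA 3 but 0.56 to 5.77 CPM in the other 4 DHCA libraries, against 0.569 to 3.10 CPM in sham. FOSL2 had 0.62 (SE 0.16) and FOS 1.13 (SE 0.68, adjusted p = 0.761), and the call was lost without Sham 6 (adjusted p = 0.0829). FOS was at 74.1 CPM in Sham 1, above all DHCA libraries (19.4 to 64.6 CPM), and every other sham library lay below all of DHCA. The member lower when adjusted over the list alone was ARC, also an activity-dependent gene and named after its value was seen (log2 fold change -1.22, SE 0.37, edgeR adjusted p = 0.0443 over the list alone). Spiny projection neuron markers were called higher (26 tested, median 0.13, adjusted p = 0.00436; adjusted p = 0.657 with an estimated correlation) with 0 members passing over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. Without Sham 4 the direction turned to lower with adjusted p = 0.484. Nuclear-encoded respiratory chain genes were called higher (52 tested, median 0.14, adjusted p = 0.0403; adjusted p = 0.663 with an estimated correlation), with 0 members over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. That call was lost without Sham 1 (adjusted p = 0.49), Sham 5 (0.201), DHCA 1 (0.102) or DHCA 3 (0.0641), and with Sham 1, Sham 4 and Sham 5 left out the list was called lower (adjusted p = 0.0114; adjusted p = 0.377 with an estimated correlation). Sham 1 and Sham 5 are the libraries with the smallest mitochondrial share, 4.01% and 7.30%.

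The lists called lower after DHCA were those of endothelium, fibroblasts, oligodendrocyte precursors and the cell cycle. Endothelial markers fell (14 tested, median -0.53, adjusted p = 0.027; adjusted p = 0.145 with an estimated correlation), with 0 members over all genes (1 higher and 4 lower at an unadjusted p under 0.05), and 1 higher and 1 lower when adjusted over the list alone. TEK had -0.95 (SE 0.29), VWF -0.70 (SE 0.32), ESAM -0.53 (SE 0.19) and TIE1 -0.52 (SE 0.23). The endothelial call was lost without Sham 1 (adjusted p = 0.162) and without DHCA 4 (0.0942). Fibroblast markers fell (11 tested, median -0.33, adjusted p = 0.00563; adjusted p = 0.145 with an estimated correlation), with 0 members over all genes and 0 when adjusted over the list alone (4 lower at an unadjusted p under 0.05). All 11 fold changes were negative, among them those of the collagen genes COL1A1 (-0.96, SE 0.36) and COL1A2 (-0.57, SE 0.24). With Sham 1, Sham 4 and Sham 5 left out, adjusted p was 0.327 for the endothelial, 0.158 for the fibroblast and 0.684 for the oligodendrocyte precursor list. Sham 1 and Sham 5, with mitochondrial shares of 4.01% and 7.30%, had the highest endothelial marker shares of the 12 libraries, 0.0684% and 0.0594%, and the highest precursor marker shares, 0.273% and 0.282%. Oligodendrocyte precursor markers fell (12 tested, median -0.27, adjusted p = 0.0376; adjusted p = 0.623 with an estimated correlation), with 0 members over all genes and, also the 1 gene at an unadjusted p under 0.05, GPR17 (-0.95, SE 0.24), a receptor gene of maturing precursors, lower when adjusted over the list alone. The precursor call was lost without Sham 1 (adjusted p = 0.103), Sham 2 (0.172), Sham 4 (0.0554), Sham 5 (0.0802), DHCA 1 (0.0527), DHCA 4 (0.0993), DHCA 5 (0.153) or DHCA 6 (0.0986). Precursor marker shares were 0.207% to 0.282% in Sham 1, Sham 2, Sham 5, DHCA 2 and DHCA 3, where oligodendrocyte markers took 2.78% to 6.42%. Elsewhere these shares were at most 0.176% and 1.535%. Cell cycle genes fell (23 tested, median -0.27, adjusted p = 0.0436; adjusted p = 0.623 with an estimated correlation), with 0 members over all genes and 0 when adjusted over the list alone (1 higher and 1 lower at an unadjusted p under 0.05). The lower one was TPX2 (-0.54, SE 0.20), and CDK1 had -0.59 (SE 0.30, adjusted p = 0.701). The cell cycle call was lost with the numbers in the titles as a block (adjusted p = 0.0612) and without Sham 3 (adjusted p = 0.145), Sham 4 (0.0762), Sham 6 (0.126), DHCA 1 (0.0719) or DHCA 3 (0.106).

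The other 16 tested lists were not called by camera. Adjusted p was 0.642 for heat shock genes, with DNAJB1 at 0.54 (SE 0.16) and HSPH1 at 0.068 (SE 0.18), and 0.878 for the unfolded protein response, with TRIB3 at 2.06 ± 1.09 CPM in sham and 5.32 ± 1.33 CPM in DHCA, a list whose median of -0.085 differs in sign from its mean and test. It was 0.071 for cholesterol synthesis, 0.0872 for antigen presentation, 0.642 for complement and phagocytosis, 0.489 for synaptic genes, 0.468 for mitochondrially encoded messenger RNAs, 0.55 for astrocytes, 0.192 for microglia, 0.15 for oligodendrocytes, 0.468 for mural cells, 0.276 for choroid plexus and ependyma, 0.114 for neutrophils and monocytes, 0.276 for lymphocytes, 0.824 for striatal interneurons and 0.0757 for cortical glutamatergic neurons. The striatal interneuron list had a median of -0.0012, below 0, while its test pointed up. In these 16 lists 0 members passed the edgeR test over all genes, with 8 higher and 14 lower at an unadjusted p under 0.05. When adjusted over the list alone, TRIB3 was higher, SALL1 was lower, and 3 cortical glutamatergic genes, with SLC17A7 and NEUROD2 among them, were lower. The fall of both rests on Sham 4, with 838 CPM of SLC17A7 and 127 CPM of NEUROD2 against at most 7.99 and 6.66 CPM elsewhere, and without that library their log2 fold changes were -0.12 and -0.41 and the adjusted p of the list was 0.441. Leaving out 1 library brought a call for cholesterol synthesis in 7 of 12 fits, for neutrophils and monocytes and for cortical glutamatergic neurons in 6 each, for antigen presentation and oligodendrocytes in 4 each, for choroid plexus and ependyma in 2 and for microglia in 1. With Sham 1, Sham 4 and Sham 5 left out, 8 of the 16 were called, among them microglia (lower, adjusted p = 0.00211) and neutrophils and monocytes (higher, adjusted p = 0.00397). With an estimated correlation in that fit, 0 of the 8 were called, and adjusted p was 0.241 for microglia and 0.119 for neutrophils and monocytes. SALL1, a transcription factor gene of homeostatic microglia, had -0.62 (SE 0.17, adjusted p = 0.235) and CX3CR1, the fractalkine receptor gene, -1.26 (SE 0.40, adjusted p = 0.365). CX3CR1 was at 5.43 CPM in Sham 1, while every other sham library lay above the highest DHCA value of 14.4 CPM.

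Cold and red cell transcripts had too few tested members for a list test. RBM3, a cold-induced RNA-binding protein gene, was at 33.8 ± 8.98 CPM in sham and 69.1 ± 14.6 CPM in DHCA (log2 fold change 1.03, SE 0.21, adjusted p = 0.0704), and passed when adjusted over the list alone. CIRBP, the other member of that list, had 0.041 (SE 0.17, adjusted p = 0.963). HBB, which encodes beta globin, had -1.64 (SE 0.39, adjusted p = 0.14), and 1 of the 4 tested red cell genes passed lower when adjusted over the list alone. Of genes fixed by name, GFAP had -0.29 (SE 0.27, adjusted p = 0.823), MBP -0.040 (SE 0.57, adjusted p = 0.993), PENK -0.058 (SE 0.51, adjusted p = 0.986), PPP1R1B -0.053 (SE 0.64, adjusted p = 0.99), DRD1 0.43 (SE 0.66, adjusted p = 0.874) and DRD2 -0.0039 (SE 0.72, adjusted p = 0.999). The DRD1, DRD2, PPP1R1B and PENK values include Sham 4, at 1.14, 0.284, 13.1 and 44.3 CPM. The other sham libraries had 204 to 353, 95.8 to 290, 924 to 2146 and 498 to 1422 CPM. DHCA had 209 to 369, 86.3 to 236, 771 to 1522 and 345 to 859 CPM. MBP was at 24118 CPM in DHCA 3 and 1532 to 9598 CPM in the other DHCA libraries. Over the fits without 1 library, DRD2 ran from -0.28 to 0.21 and PPP1R1B from -0.32 to 0.17. PENK ran from -0.32 to 0.28 and MBP from -0.76 to 0.17. IL6 (40 counts summed in each group), TNF (21 in sham and 13 in DHCA) and TTR (114 in sham and 23 in DHCA) had too few counts to test, and no gene ID carried the name IL1B or CLDN5.

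The share of counts taken by cell type markers showed how alike the tissue samples were. In Sham 4, spiny projection neuron transcripts were nearly absent and a transcript of glutamatergic neurons was abundant. DRD1, DRD2 and PPP1R1B were at 1.14, 0.284 and 13.1 CPM there, against 204 to 369, 86.3 to 290 and 771 to 2146 CPM in the other 11 libraries. SLC17A7, the vesicular glutamate transporter of cortical neurons, was at 838 CPM in Sham 4 and 2.15 to 7.99 CPM elsewhere, and its group difference (log2 fold change -5.11, SE 1.49, adjusted p = 0.282) rests on that library. Spiny projection neuron markers took 0.674 ± 0.336% of counts in sham and 0.703 ± 0.188% in DHCA (SD, n = 6; exact permutation p = 0.874, adjusted p = 0.996). The difference of 0.0292 percentage points turned to -0.0907 without Sham 4 (exact permutation p = 0.426), and to -0.00602 without DHCA 1 and -0.00656 without DHCA 4.

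**Figure D3:**
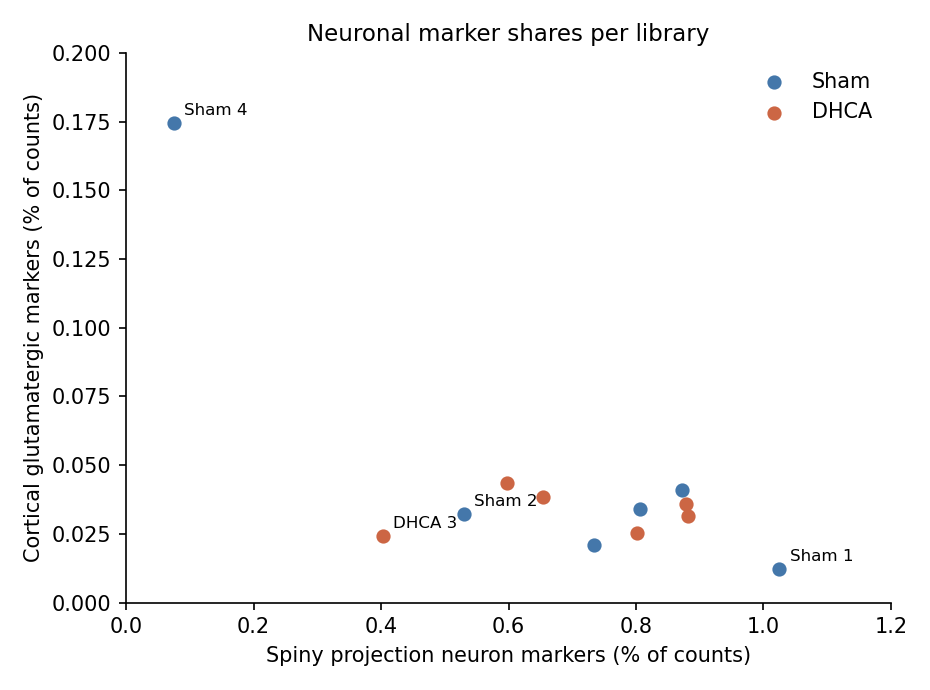
Each point is one library, with the share of its counts in spiny projection neuron markers on the horizontal axis and in cortical glutamatergic markers on the vertical axis, both in percent. Sham 4 lies apart at 0.0743% and 0.174%, and the other 11 libraries have at least 0.403% spiny projection neuron markers and at most 0.0434% glutamatergic markers.

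Fibroblast and red cell transcripts had the smallest p among the 16 shares. Fibroblast markers took 0.071 ± 0.0104% of counts in sham and 0.0547 ± 0.0064% in DHCA (exact permutation p = 0.013, adjusted p = 0.139), and red cell transcripts 0.0236 ± 0.00891% and 0.0131 ± 0.00197% (exact permutation p = 0.0173, adjusted p = 0.139). None of the 16 shares passed after adjustment, and 2 had an unadjusted p under 0.05. Without Sham 1 the red cell share passed and without Sham 2 the fibroblast share did (both adjusted p = 0.0346). Oligodendrocyte markers took 2.24 ± 1.11% in sham and 2.29 ± 2.16% in DHCA (exact permutation p = 0.968), with 6.42% in DHCA 3. The near equality of these means rests on that library, since the difference of 0.0478 percentage points turned to -0.779 without it (exact permutation p = 0.232), and the sign also turned without Sham 3 (-0.176), Sham 4 (-0.0927), Sham 6 (-0.181) or DHCA 2 (-0.0513). Endothelial, microglial and neutrophil or monocyte shares had exact permutation p of 0.156, 0.134 and 0.779.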

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

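Of 190 groups of 6 values examined for a library set apart (20 library measures and 75 genes, in each group), 16 held one, and chance gives about 1 in 20. The value given for each is the gap between that library and its nearest neighbour as a part of the range of the group, on the log2 scale for genes. The tests of explanations for Sham 4 were chosen after its profile was seen.

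Sham 4 accounted for 6 of the 16: DRD1 (0.903), PPP1R1B (0.835), DRD2 (0.833), SLC17A7 (0.82), PENK (0.698) and the share of cortical glutamatergic markers (0.824), which was 0.174% of its counts (95% exact binomial interval 0.171% to 0.178%). Of the 26 spiny projection neuron markers, 22 were lowest in Sham 4, and poor RNA or low depth is argued against by the astrocyte markers, whose median deviation from the other libraries was -0.222 on the log2 scale (SD 0.393) where that of the spiny markers was -3.52. A swap with a DHCA library is argued against too, as far as both regions respond alike, since on the 20 genes with the smallest p in a fit without Sham 4 and the DHCA library in question, placed from 0 (mean of the other sham libraries) to 1 (mean of the other DHCA libraries), Sham 4 lay at medians of -0.381 to -0.307 and the DHCA libraries at 0.649 to 1.19, with a smallest median difference of 0.966 (SD 0.367, DHCA 6). A candidate explanation is tissue from a region with glutamatergic neurons, such as cortex, since 11 of the 12 glutamatergic markers were highest in Sham 4, with NEUROD2 at 127 CPM and NEUROD6, named after its value was seen, at 122 CPM. The labels place Sham 4 in the striatum with the rest. The spiny markers, with a median deviation of -3.52, argue against the same tissue content as in the other libraries. A sample exchanged with one from outside these 12 stays open, and which region Sham 4 came from was not tested beyond the glutamatergic markers.

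Sham 1 stood apart for HSPH1 (154 CPM against 263 to 338 in the other sham libraries; 0.68) and TNFAIP6 (0.388 CPM, with 1.35 CPM or more in the others; 0.651). The TNFAIP6 value is 1 count, in a library where even 0 counts allow up to 1.16 CPM, so that gap is not read further. Sham 5, the shallowest library, had counts in 16048 genes against 18128 or more in the other sham libraries (0.64). Sham 2 was low for COL1A2 (63.6 against 117 to 160 CPM; 0.657) and for the fibroblast share (0.051%, 95% exact binomial interval 0.0497% to 0.0522%; 0.67). DHCA 3 was high for FKBP5 (298 against 170 to 204 CPM; 0.67), low for FBLN1 (5.22 against 8.33 to 10.7 CPM; 0.649) and low for the striatal interneuron share (0.0223%, 95% exact binomial interval 0.0212% to 0.0234%; 0.637). DHCA 6 was low for PIK3AP1 (50.1 against 60.6 to 63.1 CPM; 0.82) and OSMR (16.9 against 30.4 to 41.6 CPM; 0.654). The intervals cover counting error only.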

How the results depend on the processing

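Alternatives that leave out several libraries, add marker shares as covariates or join sample weights with leaving out Sham 4 were chosen after seeing the data. Across the 75 named genes and all alternatives, 1594 values stayed on their side of the threshold with the same direction, 144 same-direction values no longer passed, 75 newly passed and 58 reversed; the cause was not tested unless stated. The 26 called genes became 26 with DESeq2 size factors, 23 with upper-quartile factors, 27 with limma-voom, 29 without a filter, 27 with the 1 CPM filter, 26 without mitochondrial and red cell genes and 29 with marker shares as covariates, and 26, 23, 21, 25, 26, 26 and 21 of the original 26 were among them. Only 4 genes were lower with limma-voom. In the order total, higher, lower and log2 fold change of at least 1, the calls were 181, 111, 70 and 122 with the DESeq2 Wald test, 207, 129, 78 and 116 with sample quality weights, 189, 112, 77 and 106 with such weights and no Sham 4, 6, 5, 1 and 6 at adjusted p under 0.01, 12, 9, 3 and 12 without Sham 1 and Sham 5, and 1, 1, 0 and 1 without Sham 1, Sham 4 and Sham 5, where fewer samples were tested. In that last fit 816 genes had an unadjusted p under 0.05. Sample weights gave Sham 1 the lowest weight, 0.19. Leaving out each library gave 9 to 51 calls, 7 to 28 higher, 1 to 23 lower and 9 to 48 with a log2 fold change of at least 1. Called lists numbered 15 to 21 when each library was left out, 6 with fry, 0 with an estimated correlation and 1 (glucocorticoid-induced genes, adjusted p = 0.039) with an estimated correlation and without Sham 1, Sham 4 and Sham 5. Of the 16 lists, 9 were called without any 1 library and 11 without those 3, when 8 further lists were called. The spiny neuron list, with adjusted p from 0.000162 to 0.484 over the left-out libraries, reversed without those 3 libraries (0.284, and 0.827 with an estimated correlation), as did the respiratory chain list (0.0114 and 0.377, and 0.182 without Sham 1 and Sham 5). Shares that passed numbered 0 to 1 over the left-out libraries. Reversed log2 fold changes, none past the threshold, were -0.0097 for CIRBP with upper-quartile factors; 0.82, 1.32 and 0.41 for PPP1R1B, DRD2 and PENK with limma-voom; -0.10, 0.0023, 0.31, 0.56, 0.29 and 0.012 for HSPH1, GFAP, PPP1R1B, DRD2, PENK and MBP with sample weights; and -0.12, 0.025, 0.0058 and 0.043 for HSPH1, GFAP, PENK and MBP with weights and no Sham 4. DRD2 had 0.029 without a filter and PPP1R1B and DRD2 0.19 and 0.32 with the covariates. HSPH1, GFAP, DRD1 and MBP had -0.13, 0.19, -0.05 and 0.41 without Sham 1, Sham 4 and Sham 5, and HSPH1, GFAP, PPP1R1B, DRD2, PENK and MBP had -0.085, 0.045, 0.23, 0.39, 0.37 and 0.46 without Sham 1 and Sham 5. Over the left-out libraries the ranges were -0.053 to 0.14 for HSPH1, -0.057 to 0.14 for CIRBP, -0.022 to 0.45 for VEGFA, -0.32 to 0.17 for PPP1R1B, -0.28 to 0.21 for DRD2, -0.32 to 0.28 for PENK and -0.76 to 0.17 for MBP. Depth limits low genes most in Sham 5, where 0 counts allow up to 1.99 CPM.

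No clear pairing of the libraries by the numbers 1 to 6 in the titles was seen. Deviations of same-numbered libraries correlated between -0.388 and 0.338, with 2 of 6 above 0.1, and 1 of the 12 libraries correlated best with its own number. Differences in depth and tissue content between libraries also enter these correlations, so a shared day, litter or batch is not excluded. With these numbers as a block, 8 genes were called, 7 higher and 1 lower, and 8 with a log2 fold change of at least 1, 7 of the 8 being among the 26. Under the block 16 lists were called, 15 of them among the original 16, with the cell cycle list lost (0.0612) and the cortical glutamatergic list gained (0.0246). PPP1R1B, DRD2 and PENK reversed under the block (0.20, 0.22 and 0.17).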

Other observations

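The tests of cell content for the myeloid and vascular genes were chosen after the results were seen, as were the exact tests of the solute carrier and ACVRL1 sets. The camera tests of these sets and the comparison with other splits of the libraries were set before their results were seen.

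The real split of the libraries called 26 genes, the highest of 99 other random splits called 1, and 1 of the 100 splits, the real one, reached 26. Of the 462 distinct splits 100 were run, so chance alone is unlikely for the number of genes but not excluded. For the lists chance stays open. The real split called 16, the highest other split 17, and 7 of 100 splits called at least as many.

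IRF4, SLA, PIK3AP1 and TLR2 (the last named after its value was seen; log2 fold change 1.64, SE 0.28, adjusted p = 0.0323) are genes of immune cells and rose in DHCA by at least 1.41 on the log2 scale. More neutrophils or monocytes from blood are argued against as the whole source by their 5 tested transcripts, whose median was 0.157 (SD 0.292) and highest value 0.622. A smaller rise of such cells stays open, since 4 of the 5 lay above 0, VCAN at 300.4 CPM in sham is also a precursor marker whose level would hide it, and transcripts too low to test went both ways (S100A8 0.835 to 0.586, S100A9 0.492 to 0.972, S100A12 0.182 to 0.523 and IL1R2 0.601 to 1.66 CPM; VCAN and these 4 were named after their values were seen). More microglia in the homeostatic state are argued against as the whole source by the 16 homeostatic markers, with a median of -0.143 (SD 0.495). A change of state in resident immune cells was not tested. These markers cannot tell such a change from one in cell number, so more microglia in another state stay open.

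PCDH12, ACVRL1, SLC52A3, SLC19A3 and SLC22A6 fell by at least 1.37 on the log2 scale. Less endothelium in the DHCA samples is argued against as the whole cause by the 14 endothelial markers, whose median was -0.527 (SD 0.501) with none below -0.95, but 10 of them were negative and a smaller loss stays open. With mural markers, which had a median of 0.09, the median of 25 was -0.174 (SD 0.445), so less vascular tissue as a whole is argued against in the same way. Less meningeal tissue is argued against as the whole cause by the fibroblast markers, with a median of -0.333 (SD 0.282), although all 11 lay below 0 and a small loss of that tissue stays possible. Less choroid plexus or ependyma was not tested as a cause and stays open. All 7 tested markers of that list lay below 0, with a median of -0.145 (camera adjusted p = 0.276, and 0.0355 without Sham 4). TTR, too low to test, summed to 114 counts in sham and 23 in DHCA. Which cells the transporter transcripts came from was not tested, and effects of bypass, cooling and arrest cannot be separated with these 2 groups.

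The hypothesis that solute carrier genes fall as a class was not borne out. The 259 tested SLC genes other than SLC52A3, SLC19A3 and SLC22A6 had a median log2 fold change of -0.0056, with 128 above 0, and camera of limma gave them the direction up with p = 0.604 (exact permutation p = 0.236 for their mean log2 CPM relative to all tested genes, which was 0.038 higher in DHCA). The hypothesis that transcripts downstream of ACVRL1 fall was left open by the 10 tested genes, with 2 above 0 and a median of -0.214, to which camera of limma gave the direction down with p = 0.296 (exact permutation p = 0.654 for the same kind of mean, which was lower by a difference of -0.057). Setting a bound at that p beforehand was wrong, since a missed threshold in 10 genes does not exclude a small fall. ENG had -0.52 (SE 0.21, adjusted p = 0.512) and TMEM100 1.01 (SE 0.24, adjusted p = 0.154), both named after their values were seen.

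DHCA 4 had 0 counts of the Y-linked genes KDM5D and EIF1AY (named after their values were seen), which allows up to 0.402 CPM, while the other 11 libraries had 9.31 to 27.3 CPM and 8.53 to 25.1 CPM.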
